A study of Mus musculus with 14 samples.

How the data were processed

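RNA was measured by sequencing in 14 mouse libraries of the C57BL/6 background. Of these, 9 came from retinal microglia, the resident macrophages of the retina, with 3 libraries each at embryonic day 16.5 (e16.5), postnatal day 7 (P7) and the adult age P60. The other 5 came from whole retina, with 3 libraries at e16.5 and 1 library each at P7 and P60; the e16.5 libraries were made from central retina, per the labels. Per the labels, microglia were sorted from mice carrying green fluorescent protein at the Cx3cr1 locus as GFP-positive, CD45-positive, CCR2-negative cells, and their cDNA was made with a low-input amplification kit. Whole retina was extracted with a larger-scale RNA kit, and its library kit is not given in the sources used here. Sorting, genotype, RNA kit and tissue therefore differ together between microglia and whole retina. The labels describe each microglia library as a pool of animals and call the 3 of an age biological replicates; for whole retina at e16.5 they name only replicate numbers, so that p-values there measure the spread between these libraries, which can be technical.

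The deposited table lists 20902 genes, and every gene in it has a highest count of at least 10. Per the file headers it holds counts, FPKM, adjusted p-values and log2 fold changes. The counts deposited are whole numbers with different totals in each library, and since the submitters' processing notes list Salmon 0.9.1, whose gene counts are estimates, they were treated as estimated counts and rounded to whole numbers before any count test. The FPKM values deposited by the authors scale each count by gene length and depth, with a length that differs between libraries for a gene. The adjusted p-values and log2 fold changes deposited by the authors belong to 6 comparisons; the submitters' processing notes also list DESeq2 1.20.0 and the build GRCm38.p6, without saying which tool made which column. The tests reported here use the deposited counts. FPKM was used only to derive gene lengths per library, and the authors' comparison columns only to compare numbers of calls. Gene positions were taken from an annotation of build GRCm38, in which 20775 of the 20902 genes were found, among them all 454 named or listed genes.

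Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The 9 microglia libraries entered a shared fit over 16019 genes, from which the 3 age comparisons were drawn. The 3 microglia and 3 retina libraries of e16.5 entered a separate fit over 16140 genes. Standard errors (SE) of log2 fold changes were derived from the F statistics. A gene counted as highest at P7 when it passed the threshold against both other ages and was higher at P7 in both. CPM values were scaled with TMM factors over all 14 libraries and are given as mean ± SD with n = 3 libraries. Whole retina at P7 and P60 has 1 library each; it entered no test, and its values carry no error. For these, medians of log2 ratios were computed with 0.1 CPM added and placed among 10000 random gene lists of the same size, matched on mean expression.

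The 29 gene lists were fixed before the data were examined. They cover homeostatic microglia, disease-associated microglia, cell cycle, complement, apoptotic cell recognition, lysosome, cholesterol and lipid handling, glycolysis, type I interferon response, antigen presentation, inflammatory cytokines and NF-kB targets, immediate early genes, trophic and vascular growth factors, CSF1R and other survival receptors and ligands, and markers of border-associated macrophages, monocytes, neutrophils, lymphocytes, erythroid cells, rods, cones, retinal progenitors, ganglion cells, amacrine and horizontal cells, bipolar cells, Mueller glia and astrocytes, endothelial cells and pericytes, retinal pigment epithelium and lens. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. With fewer than 3 tested members, 2 lists (neutrophil and lens) were not tested. Counts of members past the threshold are given over all genes tested and, where stated, adjusted over the list alone.

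Named genes were also chosen by a rule written before the data were examined. In each comparison it takes, among genes past the threshold with an absolute log2 fold change of at least 1, at least 10 CPM in the higher group and no overlap between the groups, the 8 largest rises and 8 largest falls. Between ages, these are taken among genes above the whole retina level of the same age, and the 3 largest on each side at or below that level are named apart. Up to 3 risen and 3 fallen members of each list are named, or its 2 most abundant members where none passed. A set of 20 anchor genes is always given, and 10 genes highest at P7. Symbols of unnamed genes, clones, ribosomal, mitochondrial and histone genes were left out. Some genes below were singled out after their values were seen: Timp2, which completes the set of genes highest at P7, and list members given to fill the account of a list. Results of some genes that the rule takes are not reported here.

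The alternatives fixed before the data were examined were other scalings, other filters, DESeq2 1.42.0, limma-voom, a term for the replicate number, other sets of libraries, each library left out in turn, and other set tests. After the data had been examined, fits with the gene lengths implied by FPKM as an offset were added, in edgeR and in DESeq2. The test of lists was checked for P7 against e16.5 in 20 simulations with a list of 24 genes raised 2-fold and 24 unchanged genes. At unadjusted p under 0.05 camera found the raised list in 20 of them and the unchanged list in 0. Genes were simulated independently, so this does not check the preset correlation. The test of genes was checked on simulated counts with 200 genes changed. In the simulated comparison of P7 with e16.5, 51.5% of genes changed 8-fold, 19.4% of those changed 4-fold and 0% of those changed 2-fold were recovered over 15538 genes, with 3 false calls. The 8-fold genes were recovered in 48.5% of cases for P60 against P7 over 15553 genes, in 47% for P60 against e16.5 over 15532 genes and in 47% for microglia against retina at e16.5 over 15762 genes.

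Depth and spread set the precision. Microglia libraries held between 8996298 and 17446905 counts and retina libraries between 20469100 and 24361772. The biological coefficient of variation was 0.709 over the 9 microglia libraries and 0.463 over the microglia and retina libraries of e16.5. Pearson correlations of log CPM between libraries of a group, taken across genes, ran from 0.791 to 0.901 in microglia and from 0.991 to 0.993 in retina, and no pair of libraries agreed within sampling noise. A gene at 0 in all libraries of a group was given the floor of 3 counts over that group, and a fold against it is a lower bound. Such floors cover counting error only, since amplified reads are not independent molecules. Chance values were checked by splitting the libraries in other ways and by simulating unchanged groups against the P7 libraries.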

Results

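RNA levels of 20902 genes were compared in retinal microglia and whole retina of C57BL/6 mice at e16.5, P7 and P60. The series title concerns a disease-like state that microglia pass through in development and its independence of CSF1R, the receptor for the survival factors CSF1 and IL-34. The comparisons of ages ask which transcripts of retinal microglia differ between the embryo, the first postnatal week and the adult. Microglia libraries, 3 per age, held from 8996298 to 17446905 counts, and whole retina libraries, 3 at e16.5 and 1 each at P7 and P60, held from 20469100 to 24361772. Microglia values below are means ± SD over 3 libraries, coordinates are of GRCm38, and whole retina at P7 and P60 has no replicate. Adjusted p values of single genes are from edgeR unless another tool is named. In the genes named as the largest rises or falls, the libraries of the 2 groups did not overlap, which chance gives for 10% of genes with 3 libraries against 3.

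The sorted cells carried microglia transcripts at all 3 ages. Csf1r (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149, plus strand) stood at 3657 ± 1291, 4269.7 ± 1538 and 3112 ± 1082 CPM (SD, n = 3) at e16.5, P7 and P60. It was at 7.49 ± 0.671 CPM (SD, n = 3) in whole retina at e16.5. The pan-leukocyte gene Ptprc, which encodes CD45, stood at 989 ± 223, 923 ± 129 and 996 ± 276 CPM. Cx3cr1, whose locus carried the reporter, stood at 1147 ± 306, 1488 ± 486 and 1209 ± 399 CPM (SD, n = 3). Ccr2, the chemokine receptor gated against in the sort, was at 10.9 ± 3.25, 11.3 ± 8.20 and 10.6 ± 2.92 CPM. Transcripts of retinal neurons and glia were present as well. Relative to whole retina of the same age, the median marker of the 7 retinal cell lists stood in microglia at 8.02% ± 0.782 at e16.5, 6.70% ± 1.09 at P7 and 3.30% ± 3.43 at P60 (SD, n = 3). The single lists were unlike. At e16.5 they stood at 6.24% for 15 progenitor genes, 9.22% for 10 ganglion cell genes, 4.11% for 5 Mueller glia and astrocyte genes, 15.9% for 4 cone genes and 78.9% for 4 amacrine and horizontal genes. The 1 rod gene and the 1 bipolar gene abundant enough in retina at that age stood at 1.15% and 302%. The lists ran from 3.95% (rod) to 13.6% (cone) at P7 and from 1.19% (Mueller glia and astrocyte) to 10.2% (cone) at P60.

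Between e16.5 and P7, genes of the disease-associated microglia list rose in retinal microglia and genes of the cell cycle list fell. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand), which encodes the secreted phosphoprotein osteopontin, went from 23.5 ± 18.9 to 352 ± 151 CPM (SD, n = 3), a 14.8-fold rise. Igf1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042, plus strand), a secreted growth factor, rose 14.6-fold from 40.6 ± 15.0 to 603 ± 252 CPM. Lpl (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448, plus strand), which hydrolyses lipoprotein triglycerides, rose 4.83-fold from 174 ± 28.4 to 856 ± 300.2 CPM. The proliferation marker Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, minus strand) fell 5.05-fold, from 1329.8 ± 271 to 267 ± 47.2 CPM.

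With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 32 of 16019 genes changed between e16.5 and P7, 21 up and 11 down, all by at least 2-fold. The log2 fold change of Spp1 was 3.88 (SE 0.58, adjusted p = 0.0203) and that of Igf1 3.87 (SE 0.43, adjusted p = 0.0103). For Lpl it was 2.27 (SE 0.31, adjusted p = 0.0143). That of Mki67 was −2.34 (SE 0.30, adjusted p = 0.0126). The largest rise among genes above the whole retina level was that of Myo1e, a class I myosin, from 7.88 ± 3.15 to 129 ± 60.4 CPM (log2 fold change 4.01, SE 0.56, adjusted p = 0.0162). P3h2, a collagen prolyl hydroxylase, rose 12.9-fold, Pmp22, a membrane protein of peripheral myelin, 11.9-fold, Nceh1, a cholesteryl ester hydrolase, 8.08-fold, and Fn1, which encodes fibronectin, 4.76-fold, with adjusted p between 0.0103 and 0.0484. Beside that of Mki67, falls above the retina level included those of the kinetochore genes Cenpe (6.86-fold) and Cenpf (6.55-fold) and the spindle gene Hmmr (5.89-fold), with adjusted p between 0.0126 and 0.0244. DESeq2 called 328 genes, 159 up and 169 down, and limma-voom 60, 27 up and 33 down, while a filter of 5 CPM in 3 libraries gave 58 and a fit of only the 2 groups compared 143. EdgeR with the gene lengths of each library as an offset, added after the data had been seen, called 1 (1113 at unadjusted p under 0.05). With e16.5 replicate 1, 2 or 3 left out edgeR called 6, 10 or 11 genes, with P7 replicate 2 or 3 left out 16 or 7, with P60 replicate 2 or 3 left out 50 or 61, and with P7 replicate 1 left out 0 (1115 at unadjusted p under 0.05, 255 with DESeq2).

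**Figure D1:**
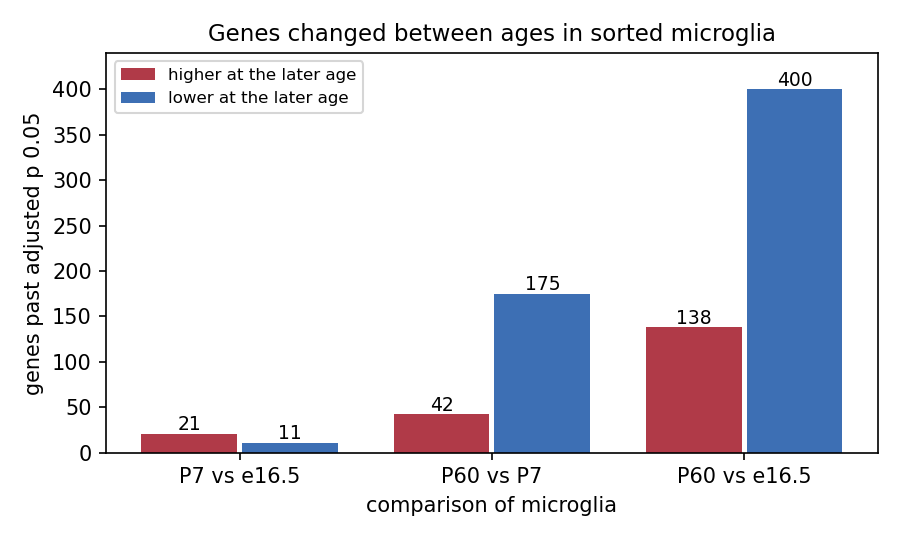
Bars show the number of genes past an adjusted p of 0.05 (edgeR quasi-likelihood) that were higher (up) or lower (down) in microglia of the later age, for the 3 comparisons of ages. The counts were 21 up and 11 down for P7 against e16.5, 42 and 175 for P60 against P7, and 138 and 400 for P60 against e16.5.

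The disease-associated list holds genes raised in microglia of diseased brain in earlier work. All 24 members had a positive log2 fold change from e16.5 to P7, with a median of 1.52. Of these, 6 passed the test over all genes (Spp1, Igf1, Lpl, Apoe, Timp2 and Ctsb), and 17 passed when adjusted over the list alone. The list rose by camera (adjusted p = 8.32e-25), also with an estimated correlation (adjusted p = 0.0435). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, minus strand), a lipid-carrying apolipoprotein, rose 4.69-fold from 431 ± 123 to 2054 ± 650.0 CPM (SD, n = 3). The lysosomal protease gene Ctsb (ENSMUSG00000021939, chromosome 14, 63122462 to 63145923, plus strand) rose from 2545 ± 310.1 to 7876 ± 2588 CPM (log2 fold change 1.61, SE 0.28, adjusted p = 0.0484). Members that did not pass in edgeR's test over all genes include the growth factor gene Csf1 (51.4 ± 16.7 to 227 ± 99.0 CPM, adjusted p = 0.0786) and the integrin gene Itgax (112 ± 91.0 to 213 ± 65.6 CPM, adjusted p = 0.793). Others were the receptor kinase gene Axl (204 ± 34.9 to 433 ± 123 CPM, adjusted p = 0.354), the lectin gene Clec7a (94.9 ± 36.0 to 182 ± 122 CPM, adjusted p = 0.842) and the lipid receptor gene Trem2 (106 ± 35.8 to 152 ± 23.0 CPM, adjusted p = 0.835).

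Homeostatic genes showed no common direction at this step. None of the 20 members of that list passed edgeR's test over all genes (2 fell when adjusted over the list alone), the median log2 fold change was 0.23, and camera gave an adjusted p of 0.838. The microglial surface gene Tmem119 (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516, minus strand) stood at 381 ± 129.7 and 136 ± 44.2 CPM (adjusted p = 0.223). The purinergic receptor gene P2ry12 was at 2151 ± 419 and 1736 ± 528 CPM (adjusted p = 0.941) and the transcription factor gene Sall1 at 380.2 ± 21.6 and 599 ± 169.7 CPM (adjusted p = 0.608 with edgeR, SD, n = 3). The most abundant member, Sparc, a matrix glycoprotein, was at 3559 ± 884 and 5702 ± 2038 CPM (adjusted p = 0.640).

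**Figure D2:**
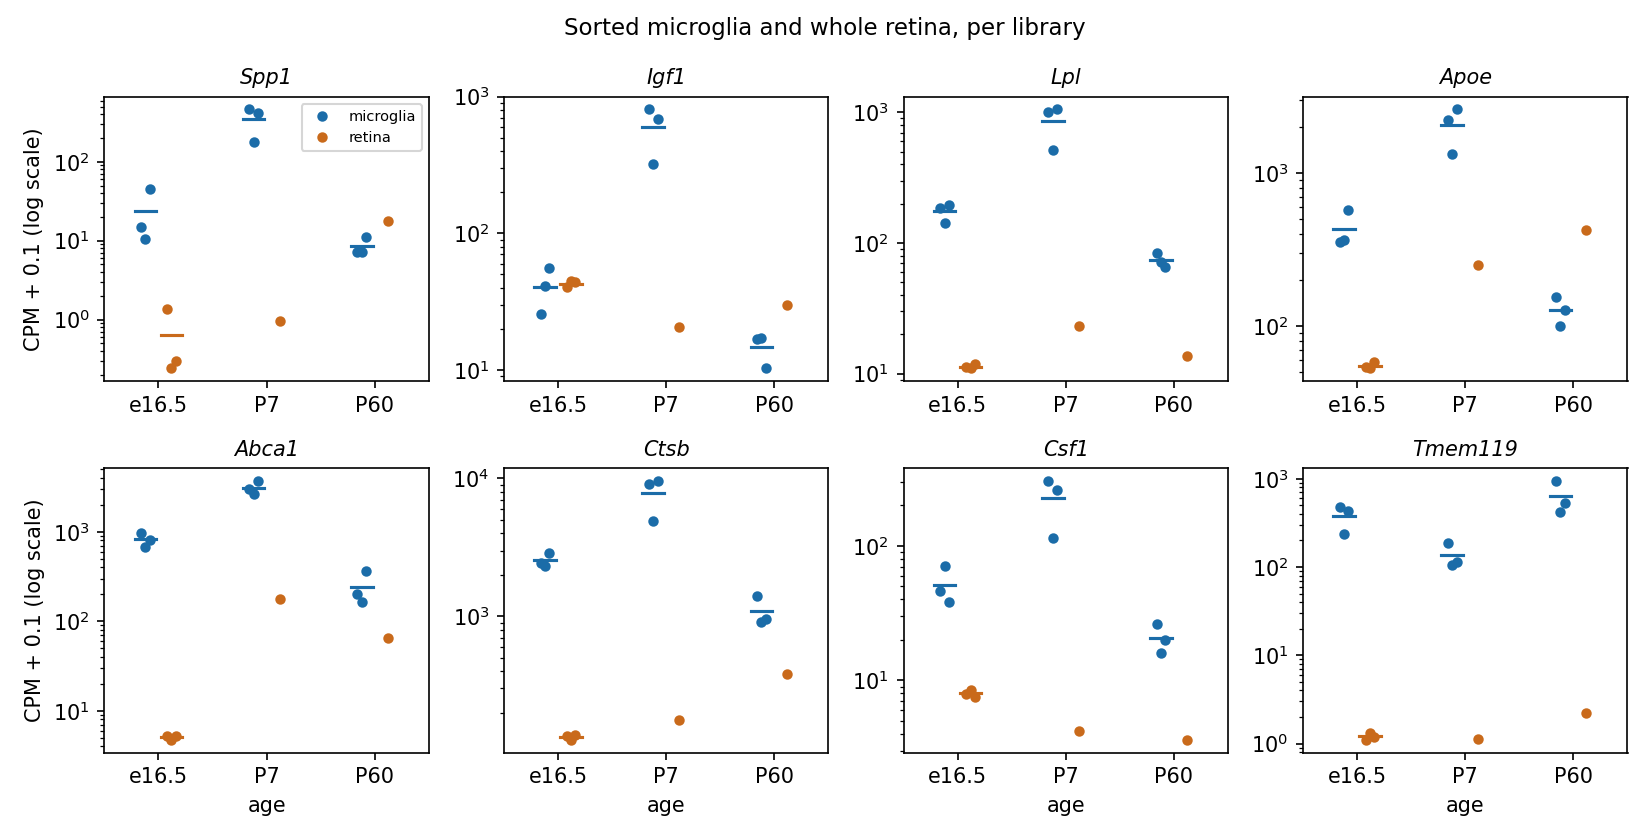
Points are CPM (with 0.1 added, log axis) of single libraries of microglia (blue) and whole retina (orange) at e16.5, P7 and P60 for 8 genes, and lines mark group means. Microglia means of Spp1 were 23.5, 352 and 8.43 CPM and those of Tmem119 were 381, 136 and 630.3 CPM at the 3 ages.

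Cell cycle genes fell together. Of 32 members, 4 fell past the test over all genes (Cenpe, Cenpf, Top2a and Mki67) and 23 when adjusted over the list alone. All 32 had a negative log2 fold change, and the median was −2.08 (camera adjusted p = 2.655e-29, adjusted p = 0.0128 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell 6.51-fold from 636 ± 168 to 99.0 ± 18.0 CPM (SD, n = 3). Whole retina showed the same sign, with a median log2 ratio of −3.385 for this list between P7 and e16.5, at percentile 0 of 10000 random lists. At e16.5, 8.02% of the whole retina level amounted to 19.5% of the microglia level for the median member.

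Several smaller shifts were called by camera and were not called with an estimated correlation. Lysosome genes had a median log2 fold change of 0.44, with 0 of 22 past edgeR's test over all genes and 5 up when adjusted over the list alone. The list had a camera adjusted p of 0.000644 (adjusted p = 0.396 with an estimated correlation). The cathepsin gene Ctss stood at 4166 ± 853 and 5799 ± 1811 CPM and the granulin precursor gene Grn at 1187 ± 32.6 and 2268 ± 598 CPM (SD, n = 3). Antigen presentation genes had a median of 0.60, with 0 of 14 past edgeR's test over all genes and 1 up when adjusted over the list alone (camera adjusted p = 0.00576, adjusted p = 0.199 with an estimated correlation). Complement genes had a median of 0.62, with 0 of 10 by either adjustment (camera adjusted p = 0.0127, adjusted p = 0.311 with an estimated correlation). The list of CSF1R and other survival receptors and ligands had a median of 0.44, with 0 of 15 over all genes and 1 up when adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.272 with an estimated correlation). Immediate early genes had a median of −0.71 (0 of 21 by either adjustment, camera adjusted p = 0.0106, adjusted p = 0.679 with an estimated correlation). Their most abundant member, the transcription factor gene Egr1, varied between libraries, with 5797 ± 4480.3 and 3466 ± 1902 CPM. Cholesterol and lipid genes were mixed. The sterol exporters Abcg1 (log2 fold change 1.97, SE 0.30, adjusted p = 0.0203) and Abca1 (1.90, SE 0.31, adjusted p = 0.0377) rose. The list median was −0.42, 2 members were up and 5 down when adjusted over the list alone, and camera gave an adjusted p of 0.0509.

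In the sorted microglia, the medians of 6 of the 7 retinal cell lists had the sign they had in whole retina between these ages, the exception being amacrine and horizontal cells (−0.68 against 1.752). Rod genes had a median log2 fold change of 3.27, with 3 of 15 up over all genes, namely Prph2, Rp1 and Pdc, and 12 when adjusted over the list alone (camera adjusted p = 2.94e-18, adjusted p = 0.128 with an estimated correlation). Their median log2 ratio in whole retina was 8.454. Rp1, a microtubule protein of photoreceptor outer segments, went from 0.172 ± 0.149 to 106 ± 34.0 CPM in microglia, against 2314 CPM in whole retina at P7. Progenitor genes fell, Fgf15 and Ccnd1 of 14 over all genes and 9 when adjusted over the list alone (median −2.55, camera adjusted p = 1.92e-16, adjusted p = 0.00647 with an estimated correlation). Ganglion cell genes had a median of −2.46, with 0 of 11 over all genes in edgeR and 1 up and 5 down when adjusted over the list alone (camera adjusted p = 8.95e-05, adjusted p = 0.108 with an estimated correlation). Cone genes had a median of 1.2, with 0 of 7 over all genes and 1 up when adjusted over the list alone (camera adjusted p = 0.00576, adjusted p = 0.285 with an estimated correlation). Bipolar genes had a median of 1.74, with 0 of 8 by either adjustment (camera adjusted p = 0.00113, adjusted p = 0.285 with an estimated correlation). Mueller glia and astrocyte genes had a median of 1.15, with 0 of 6 over all genes and 2 up when adjusted over the list alone (camera adjusted p = 0.001, adjusted p = 0.22 with an estimated correlation). Over all genes called between these ages, 6 of the 21 that rose and 6 of the 11 that fell were at or below the whole retina level of the age where they were higher. Among these were the rises of Samd7, Prph2 and Rp1 and the falls of Fgf15 and Sox11.

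The remaining lists were not called by camera between e16.5 and P7. Median log2 fold changes were 0.35 for apoptotic cell recognition (adjusted p = 0.131), 0.03 for glycolysis (0.779), −0.81 for type I interferon response (0.693), −0.13 for inflammatory genes (0.424) and −0.14 for trophic factors (0.222). They were 0.33 for border-associated macrophages (0.693), 0.49 for monocytes (0.131), 0.26 for lymphocytes (0.693) and −0.06 for erythroid genes (0.647). Of the retinal lists they were −0.68 for amacrine and horizontal cells (0.0566), −0.57 for endothelial cells and pericytes (0.694) and 0.40 for pigment epithelium (0.694). Fn1 was the member of the monocyte list that passed over all genes. Adjusted over the list alone, 1 inflammatory and 2 monocyte genes were up, 1 border-associated macrophage and 1 amacrine gene were down, and 1 endothelial gene was up and 1 down. Median, mean and test differed in sign for the glycolysis, inflammatory, trophic, border-associated macrophage, erythroid and endothelial lists. Of the untested lists, the neutrophil gene Csf3r stood at 258 ± 58.5 and 328 ± 90.6 CPM and the lens gene Cryba1 at 2.81 ± 1.47 and 6.23 ± 5.49 CPM (SD, n = 3).

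Between P7 and P60, 13 of 24 disease-associated genes and 7 of 15 glycolysis genes fell in retinal microglia. Spp1 dropped 40.5-fold to 8.43 ± 2.33 CPM, Igf1 40.1-fold to 14.6 ± 3.81 CPM, Apoe 15.7-fold to 127 ± 27.4 CPM and Lpl 11.3-fold to 73.7 ± 9.79 CPM (SD, n = 3). The homeostatic gene Tmem119 rose 4.74-fold to 630.3 ± 275 CPM, and Selplg, which encodes a selectin ligand, 2.57-fold from 173 ± 37.3 to 433 ± 69.6 CPM. Of the other homeostatic genes, the Fc receptor-like gene Fcrls fell 6.92-fold from 1536 ± 429 to 216 ± 79.1 CPM and Sparc 3.42-fold to 1620.1 ± 298 CPM.

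With edgeR, 217 of 16019 genes changed between P7 and P60, 42 up and 175 down (61 up and 99 down with libraries scaled by total counts alone). The log2 fold changes were −5.34 for Spp1 (SE 0.63, adjusted p = 0.00343), −5.32 for Igf1 (SE 0.46, adjusted p = 0.000314) and −3.98 for Apoe (SE 0.34, adjusted p = 0.000291). They were 2.25 for Tmem119 (SE 0.39, adjusted p = 0.0204) and −2.79 for Fcrls (SE 0.36, adjusted p = 0.00478). Scd2 (ENSMUSG00000025203, chromosome 19, 44293674 to 44306864, plus strand), a fatty acid desaturase, fell 24.1-fold from 779 ± 218 to 31.3 ± 10.8 CPM (adjusted p = 0.000291). The semaphorin receptor gene Plxnc1 fell 41.6-fold, the G protein regulator gene Rgs7bp 35.0-fold and the late endosome GTPase gene Rab7b 34.4-fold, with adjusted p between 0.0161 and 0.0426. St8sia2, a polysialyltransferase, went from 11.5 ± 13.8 to 0.0286 ± 0.0496 CPM. Tmem254a, at 11.7 ± 9.09 CPM, fell at least 129-fold to 0 counts, although reads may be split with near-identical copies of this gene.

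Among the rises was that of the transcription factor gene Cebpd (ENSMUSG00000071637, chromosome 16, 15887286 to 15891031, plus strand), 12-fold from 19.5 ± 6.01 to 228 ± 131 CPM (log2 fold change 3.58, SE 0.50, adjusted p = 0.00702). H2-Aa, an MHC class II chain of a multigene family, went from 0.0541 ± 0.0936 to 31.7 ± 27.2 CPM (adjusted p = 0.0171). Csmd3 rose 22-fold, the sialyltransferase gene St8sia6 19.6-fold, the lipogenic gene Thrsp 15.4-fold and the interferon-induced gene Mx2 13.5-fold, with adjusted p between 0.00924 and 0.0332 in edgeR. At or below the retina level were 9 of the 42 rises, among them those of Pdzph1 and the photoreceptor genes Gnat1 and Guca1b, and 67 of the 175 falls, among them those of Fabp7, Sema6a and Mif. DESeq2 called 1254 genes, the edgeR fit with gene lengths 64, that of only the 2 groups compared 82 and that with a term for the replicate number 367. EdgeR called 143, 124 or 141 genes without e16.5 replicate 1, 2 or 3, 52, 110 or 41 without P7 replicate 1, 2 or 3, and 73 or 89 without P60 replicate 2 or 3.

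Of the 24 disease-associated genes, 13 fell over all genes between P7 and P60 and 18 when adjusted over the list alone, with a median log2 fold change of −1.86. Camera called the list (adjusted p = 3.10e-15, adjusted p = 0.191 with an estimated correlation). Beyond the genes above, Csf1 fell 10.7-fold to 20.6 ± 5.09 CPM (adjusted p = 0.00478) and Itgax 6.61-fold to 31.3 ± 10.2 CPM (adjusted p = 0.0399). Ctsb, Timp2, Cd63, Cd68, Ctsd, Ctsl and Fabp5 were also among the 13. Axl (157 ± 56.2 CPM at P60, adjusted p = 0.0598), Clec7a (112 ± 77.3 CPM, adjusted p = 0.606) and Trem2 (154 ± 45.7 CPM, adjusted p = 0.958) did not pass in edgeR.

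Of 15 glycolysis genes, 7 fell over all genes (Aldoa, Tpi1, Gapdh, Pgk1, Pgam1, Pkm and Ldha), and 1 was up and 10 down when adjusted over the list alone. The median was −1.72 (camera adjusted p = 2.48e-06, adjusted p = 0.191 with an estimated correlation). Phosphoglycerate kinase Pgk1 fell 6.27-fold from 279 ± 90.7 to 43.2 ± 11.2 CPM, phosphoglycerate mutase Pgam1 6.09-fold to 86.0 ± 25.8 CPM and pyruvate kinase Pkm 4.78-fold to 112 ± 11.7 CPM (SD, n = 3). Gapdh, Pgk1, Pgam1 and Ldha have processed pseudogenes that can share their reads, so their levels are uncertain to that extent. Of 22 lysosome genes 4 fell over all genes (Lipa, Gusb, Lamp1 and Grn) and 14 when adjusted over the list alone. Their median was −1.05 (camera adjusted p = 4.45e-06, adjusted p = 0.367 with an estimated correlation). Lamp1, a lysosomal membrane protein gene, fell 3.20-fold from 1264 ± 302 to 384 ± 32.2 CPM, and Lipa, the lysosomal acid lipase gene, 4.56-fold to 125 ± 71.1 CPM.

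Cell cycle genes had a median of −0.66, with Cdk1, Cenpe and Mcm5 of 32 down over all genes and 5 when adjusted over the list alone (camera adjusted p = 0.00451, adjusted p = 0.367 with an estimated correlation). Mki67 was at 109.7 ± 30.2 CPM at P60 (adjusted p = 0.0615 against P7). Interferon response genes had a median of 1.70 with 17 of 18 positive, while 0 passed by either adjustment in edgeR (camera adjusted p = 0.000389, adjusted p = 0.379 with an estimated correlation). Their member Ifi204 stood at 80.5 ± 28.0 and 136 ± 60.2 CPM (SD, n = 3). Immediate early genes had a median of 0.87, 1 up over all genes (Klf4, 7.29-fold) and 6 when adjusted over the list alone (camera adjusted p = 0.00451, adjusted p = 0.575 with an estimated correlation). The list of survival receptors and ligands had a median of −0.42, with Csf1 and Kit of 15 down over all genes and 5 when adjusted over the list alone (camera adjusted p = 0.0112, adjusted p = 0.367 with an estimated correlation). Apoptotic cell recognition had a median of −0.45, with 0 of 17 past the test over all genes and 1 up and 2 down when adjusted over the list alone (camera adjusted p = 0.0284, adjusted p = 0.379 with an estimated correlation). Its most abundant members, the scavenger receptor gene Lrp1 and the receptor kinase gene Mertk, stood at 755 ± 293 and 962 ± 220.1 CPM at P60 (SD, n = 3).

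The homeostatic list had no common direction, with 2 members up and 2 down over all genes, 4 and 3 when adjusted over the list alone, and a median of −0.16 (camera adjusted p = 0.988). In the cholesterol and lipid list Scd2, Abcg1 (14.5-fold) and Abca1 (12.5-fold) fell over all genes. When adjusted over the list alone 2 members were up and 6 down, and camera gave an adjusted p of 0.209. Antigen presentation had a median of 0.64 with H2-Aa up by both adjustments (camera adjusted p = 0.0529). The lymphocyte and monocyte lists had medians of 0.69 and 0.03 (camera adjusted p = 0.778 and 0.437). Complement had a median of −0.65 with 0 of 10 over all genes and 1 down when adjusted over the list alone (camera adjusted p = 0.188). Of the lists not called, median, mean and test differed in sign for trophic factors, border-associated macrophages, monocytes, amacrine and bipolar cells.

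Rod genes had a median of 2.01 between P7 and P60, with Gnat1 and Pde6a of 15 up over all genes and 6 when adjusted over the list alone (camera adjusted p = 0.0054, adjusted p = 0.575 with an estimated correlation). Gnat1, the rod transducin gene, went from 10.1 ± 5.21 to 633 ± 428 CPM in microglia and from 40.7 to 11276 CPM in whole retina. The P60 microglia libraries differed in their retinal share, which was 1.78%, 7.23% and 0.90% in replicates 1, 2 and 3. Progenitor genes had a median of −1.37 (−1.18 with genes at 0 counts held at their bound), with 1 of 14 down over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.00925, adjusted p = 0.321 with an estimated correlation). Ganglion cell genes had a median of −0.66, with Gap43 of 11 down over all genes and 1 up and 5 down when adjusted over the list alone (camera adjusted p = 0.00747, adjusted p = 0.334 with an estimated correlation). Endothelial and pericyte genes had a median of −0.74, with 0 of 5 over all genes and 1 down when adjusted over the list alone (camera adjusted p = 0.00925, adjusted p = 0.334 with an estimated correlation).

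**Figure D3:**
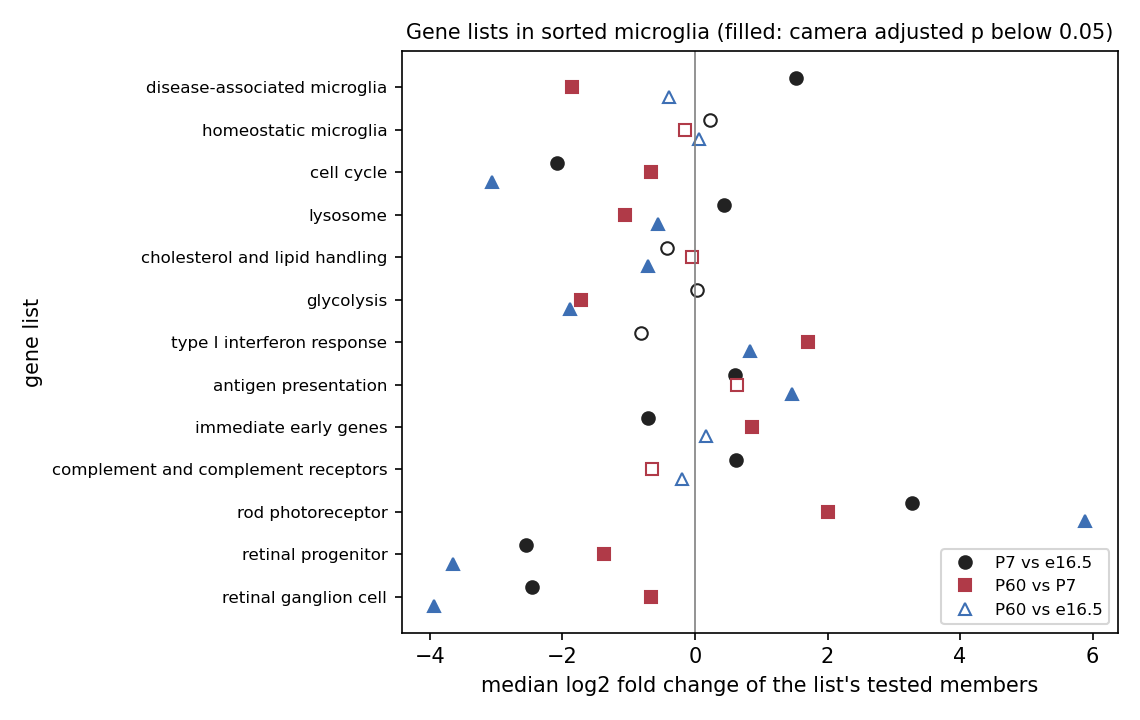
Points are the median log2 fold change of 13 gene lists in microglia for the 3 comparisons of ages, filled where camera's adjusted p was below 0.05. The disease-associated list stood at 1.52, −1.86 and −0.39 for P7 against e16.5, P60 against P7 and P60 against e16.5, and the cell cycle list at −2.08, −0.66 and −3.07.

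A set of 11 genes was highest at P7, passing the test against both other ages: Spp1, Igf1, Myo1e, Lpl, Fn1, Apoe, Abcg1, Abca1, Slc12a2, Ctsb and Timp2. They include the lipid genes Apoe, Lpl, Abca1 and Abcg1, the secreted or matrix-associated genes Spp1, Igf1, Fn1 and Timp2, and the ion cotransporter gene Slc12a2. Abca1 (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895, minus strand) stood at 822 ± 148, 3115 ± 544 and 242 ± 104 CPM at the 3 ages. Slc12a2 was at 236 ± 15.7, 841 ± 257 and 155 ± 40.4 CPM and Fn1 at 36.3 ± 11.1, 176 ± 27.3 and 19.1 ± 3.66 CPM (SD, n = 3). At P7 whole retina held 0.854 CPM of Spp1, 20.7 of Igf1, 23.2 of Lpl and 250.4 of Apoe. Timp2, a metalloproteinase inhibitor gene, was at 224 ± 39.9, 844 ± 171 and 289.9 ± 66.4 CPM and was named after its values were seen, since it completes the set.

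Of the 11, 6 belong to the disease-associated list. Independent lists of the same sizes would share 0.229 genes, and 20 simulations of unchanged groups against the shared P7 libraries gave 0. In these simulations no gene changed at either step, so that hardly any calls could overlap. Their 0 therefore does not measure how many of the 11 come from the sharing. The 3 P7 libraries are too few to be split, so part of the overlap can come from their being shared. The log2 fold changes of P7 against e16.5 and against P60 correlated across genes at 0.18 (0.50 in the simulations), with a covariance of 0.315 (0.469). Cenpe and Sox11 fell at both steps (0.12 genes for independent lists). The count of 11 was 56 with DESeq2, 20 with limma-voom, 17 with the filter of 5 CPM and 0 in edgeR with gene lengths as an offset (141 at unadjusted p under 0.05 at both steps, 41 with DESeq2). It was 1, 1 and 4 without e16.5 replicates 1, 2 and 3, 1 without P7 replicate 3, and 0 in edgeR without P7 replicate 1 (147 at unadjusted p under 0.05 at both steps, 36 with DESeq2).

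Between e16.5 and P60, 16 of 32 cell cycle genes and 9 of 15 glycolysis genes fell in retinal microglia. Mki67 fell 12-fold from 1329.8 ± 271 to 109.7 ± 30.2 CPM, the glycolysis gene Pgam1 6.59-fold from 577 ± 204 to 86.0 ± 25.8 CPM and the desaturase gene Scd2 15.6-fold from 495 ± 131 to 31.3 ± 10.8 CPM (SD, n = 3). H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823, minus strand) was at 0 counts at e16.5 and at 31.7 ± 27.2 CPM at P60, at least 423-fold higher. The lymphocyte genes Gzmb and Gzma were at 0 counts at e16.5 and P7. By mean CPM they were at least 140-fold and 22.6-fold higher at P60 than at e16.5, but neither was among the genes tested. Of the 6 other lymphocyte genes, which were tested, 4 had a positive and 2 a negative log2 fold change, and 0 passed by either adjustment. Other immune cells in the P60 sort and a change of the microglia were not tested against each other. P3h2 rose 31-fold from 7.18 ± 2.86 to 220.2 ± 47.5 CPM.

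With edgeR, 538 of 16019 genes changed between e16.5 and P60, 138 up and 400 down (189 up and 301 down with libraries scaled by total counts alone). Of these, 537 differed by at least 2-fold. The log2 fold changes were −3.58 for Mki67 (SE 0.31, adjusted p = 0.000336) and −3.96 for Scd2 (SE 0.37, adjusted p = 0.000432). That of P3h2 was 4.95 (SE 0.44, adjusted p = 0.000336). Csmd3 rose 38.8-fold, Lrguk 32.9-fold, the ephrin gene Efnb1 26.4-fold and Pmp22 23.2-fold. The thrombomodulin gene Thbd was at 0 counts at e16.5 and at 15.8 ± 23.4 CPM at P60, at least 211-fold higher. The adjusted p of these 5 genes lay between 0.00326 and 0.0431. Among the falls were the matricellular gene Cyr61 (107-fold), the cohesin protector gene Sgol2a (89.7-fold), the RNA-binding protein gene Lin28b (74.3-fold), Rgs7bp (55.2-fold) and the transcription factor gene Onecut1 (32.3-fold), with adjusted p between 0.00486 and 0.0275. The glypican gene Gpc4, at 19.8 ± 28.3 CPM at e16.5, was at 0 counts at P60, at least 219-fold lower (adjusted p = 0.0447). St8sia2 went from 17.0 ± 7.55 to 0.0286 ± 0.0496 CPM. Of the called genes, 57 of 138 rises and 260 of 400 falls were at or below the retina level of the age where they were higher. Among them were the rises of Cplx4, Prph2 and BC027072 and the falls of Tcf19, Foxn4 and Hhip. DESeq2 called 1902 genes, the edgeR fit with gene lengths 239 and that of only the 2 groups compared 227. EdgeR called 188 or 174 genes without e16.5 replicate 2 or 3, 322 without P7 replicate 1, and 341 or 340 without P60 replicate 2 or 3.

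The disease-associated list as a whole was not called between e16.5 and P60 (median −0.39, camera adjusted p = 0.190). Apoe (3.35-fold, adjusted p = 0.0120), Lpl (2.34-fold, adjusted p = 0.0478) and Ctsb (2.32-fold, adjusted p = 0.0358) fell in edgeR, and 2 of 24 members were up and 8 down when adjusted over the list alone. Of the 32 cell cycle genes, 16 fell over all genes and 23 when adjusted over the list alone (median −3.07, camera adjusted p = 2.22e-19, adjusted p = 0.0372 with an estimated correlation). Cdk1 fell 48.3-fold, Aurka 27.5-fold and Ttk 27-fold. Of 15 glycolysis genes 9 fell over all genes, with 1 up and 10 down when adjusted over the list alone (median −1.89, camera adjusted p = 4.75e-06, adjusted p = 0.0685 with an estimated correlation). In the cholesterol and lipid list Scd2, Abcg1, Abca1 and Hmgcs1 of 18 fell over all genes, with 5 down when adjusted over the list alone (median −0.71, camera adjusted p = 0.000212, adjusted p = 0.0685 with an estimated correlation). Lysosome genes had 1 of 22 down over all genes (Gusb, 2.91-fold), 3 when adjusted over the list alone and a median of −0.56 (camera adjusted p = 0.0303, adjusted p = 0.655 with an estimated correlation).

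Antigen presentation genes had a median of 1.46, with H2-Aa of 14 up over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.000331, adjusted p = 0.0790 with an estimated correlation). The lymphocyte and monocyte lists were not called, with medians of 0.92 and 0.05 (camera adjusted p = 0.520 and 0.989). Interferon response genes had a median of 0.84, with 0 of 18 over all genes in edgeR and 2 up when adjusted over the list alone (camera adjusted p = 0.00306, adjusted p = 0.496 with an estimated correlation). The homeostatic list had Cst3, a cysteine protease inhibitor, up 2.46-fold and Fcrls down 4.49-fold, 2 up and 2 down when adjusted over the list alone, and a median of 0.06 (camera adjusted p = 0.989). Single members also passed in lists that were not called. The chemokine gene Ccl2 rose 5.14-fold to 137 ± 25.9 CPM and the transcription factor gene Klf4 6.32-fold. The phagocytic receptor gene Megf10 fell 43.9-fold and the proteoglycan gene Vcan 19.9-fold. Kit, at 1.46 ± 1.22 CPM at e16.5, fell at least 16.1-fold to 0 counts. Median, mean and test differed in sign for the homeostatic, complement, inflammatory, trophic and border-associated macrophage lists.

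Rod genes stood highest at P60 in the sorted microglia, with 12 of 15 up from e16.5 over all genes and 15 when adjusted over the list alone (median 5.89, camera adjusted p = 3.77e-15, adjusted p = 0.128 with an estimated correlation). Pde6a (ENSMUSG00000024575, chromosome 18, 61220315 to 61289924, plus strand), which encodes a subunit of the rod phosphodiesterase, stood at 1.80 ± 0.382, 6.36 ± 2.16 and 77.6 ± 78.5 CPM in microglia (P60 against e16.5, edgeR log2 fold change 5.44, SE 0.80, adjusted p = 0.00562). In whole retina it was at 0.278 ± 0.113, 89.7 and 2877 CPM at the 3 ages. Progenitor genes fell, 7 of 14 over all genes and 11 when adjusted over the list alone (median −3.65, camera adjusted p = 4.81e-13, adjusted p = 0.0123 with an estimated correlation). Ganglion cell genes had 5 of 11 down over all genes, with 2 up and 7 down when adjusted over the list alone (median −3.93, camera adjusted p = 1.24e-05, adjusted p = 0.0685 with an estimated correlation). Cone genes had a median of 2.58 with 0 of 7 over all genes and 4 up when adjusted over the list alone (camera adjusted p = 0.000628, adjusted p = 0.255 with an estimated correlation). Bipolar genes had a median of 2.26 with 0 of 8 over all genes and 4 up when adjusted over the list alone (camera adjusted p = 0.0326, adjusted p = 0.496 with an estimated correlation). Endothelial and pericyte genes had a median of −1.31 with Pecam1 of 5 down over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.0329, adjusted p = 0.283 with an estimated correlation). In the Mueller glia and astrocyte list Rlbp1 and Slc1a3 rose and Dkk3 fell, with 3 up and 1 down when adjusted over the list alone (median 1.44, camera adjusted p = 0.0539). In P60 replicates 1, 2 and 3 the rod list stood at 1.47%, 7.47% and 0.893% of the whole retina level, the cone list at 5.17%, 23.7% and 1.75%, the bipolar list at 1.55%, 9.92% and 0.885% and the ganglion cell list at 4.15%, 1.80% and 1.41%.

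**Figure D4:**
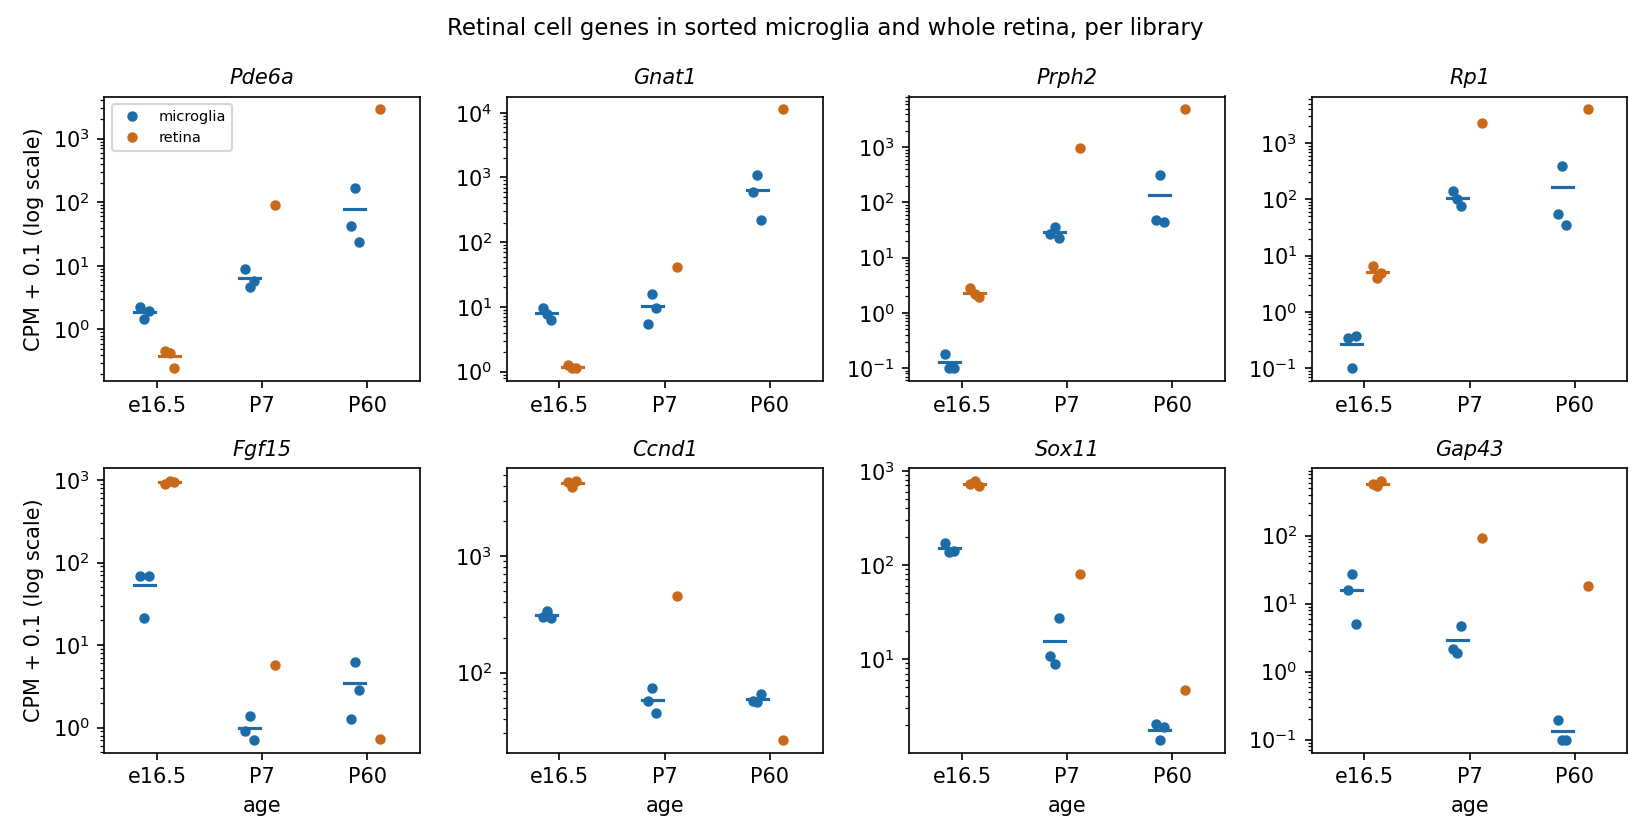
Points are CPM (with 0.1 added, log axis) of single libraries of microglia (blue) and whole retina (orange) at e16.5, P7 and P60 for the photoreceptor genes Pde6a, Gnat1, Prph2 and Rp1 and for Fgf15, Ccnd1, Sox11 and Gap43, with lines at group means. Gnat1 at P60 averaged 633 CPM in microglia and reached 11276 CPM in whole retina.

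At e16.5, the age with replicated whole retina, sorted microglia and whole retina differed in most tested genes. Cd180, a Toll-like receptor homologue, stood in microglia at 1674 ± 101 against 0.0955 ± 0.125 CPM in retina, and Rgs1, a regulator of G protein signalling, stood at 357 ± 367 CPM against 0 counts (SD, n = 3), at least 7280-fold higher. Of erythroid genes 5 of 6 and of progenitor genes 13 of 15 were lower in microglia. The beta-globin gene Hbb-bs was at 0 counts in microglia and 214 ± 114 CPM in retina, at least 2860-fold lower, and Fgf15 was at 53.2 ± 27.6 against 937 ± 44.9 CPM. Tissue, sorting, genotype, RNA kit and, per the labels, cDNA amplification of the microglia cannot be separated in this comparison.

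With edgeR 10206 of 16140 genes differed at e16.5, 5346 higher and 4860 lower in microglia, and counts with a replicate left out ranged from 8604 to 12088. The balance turned with libraries scaled by total counts alone (4679 higher and 5847 lower), with limma-voom (5307 and 5964) and without microglia replicate 1 (5566 and 5819) or 3 (5988 and 6100). Among the largest rises were Rgs1, Apbb1ip, Egr3, Egr1, Cd180, BC106175, Dyrk4 and Egr2, with adjusted p between 3.68e-06 and 0.00125. The early response transcription factor Egr1 stood at 5797 ± 4480.3 against 0.340 ± 0.165 CPM. Among the largest falls were Eif4a-ps4, Hbb-bs, Ccnb1ip1, Pgam1-ps2, Hbb-bt, Rbm3-ps, Gcat and Enho. Of these, Eif4a-ps4, Pgam1-ps2 and Rbm3-ps are processed pseudogenes and Hbb-bs and Hbb-bt near-identical copies, as BC106175 among the rises is a transcribed pseudogene, so that their counts are uncertain.

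By list, 20 of 20 homeostatic genes were higher in microglia at e16.5 (median log2 fold change 8.24), as were 9 of 9 complement genes (9.78) and 14 of 14 inflammatory genes (9.65). Also higher were 13 of 14 interferon genes (5.18), 11 of 13 antigen presentation genes (6.20) and 21 of 22 lysosome genes (3.22). Of 22 disease-associated genes 20 were higher and 1 lower (4.11), and of 21 immediate early genes 20 and 1 (5.71). Lower in microglia were 13 of 15 progenitor genes (−3.77), 9 of 12 ganglion cell genes (−3.22), 11 of 15 glycolysis genes (1 higher, −1.28), 13 of 19 cholesterol and lipid genes (4 higher, −1.71) and 5 of 6 erythroid genes (−10.01). Of 4 bipolar genes 1 was higher (0.46). Other retinal lists went both ways, with 5 of 12 rod genes higher and 3 lower (1.13), 1 and 2 of 10 amacrine and horizontal genes (0.21), 1 and 2 of 6 cone genes (−1.37) and 1 and 4 of 6 Mueller glia and astrocyte genes (−3.57). All 6 border-associated macrophage genes tested and 4 of 7 monocyte genes were higher.

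At P7 and P60 microglia and whole retina were compared by value alone. The homeostatic list stood at a median log2 ratio of microglia to retina of 7.271 at P7 and 7.787 at P60, and the disease-associated list at 5.157 and 2.901, all at percentile 100 of 10000 matched random lists. The rod list stood at −4.58 and −5.052 (percentile 0 at both ages), and the glycolysis list at −1.457 (percentile 0.13) and −3.401 (percentile 0.01). Within whole retina, the rod list stood higher by a median log2 ratio of 8.454 at P7 than at e16.5 and of 2.199 at P60 than at P7 (percentile 100 both times). The disease-associated list stood at 0.805 (percentile 95.1) and −0.156 (percentile 27.25) for the same steps, and the interferon list at 0.269 (percentile 4.58) and 1.421 (percentile 100).

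The ligands of CSF1R had low levels in whole retina. Csf1 (ENSMUSG00000014599, chromosome 3, 107741048 to 107760469, minus strand) stood at 7.90 ± 0.489 CPM (SD, n = 3) at e16.5 and at 4.09 and 3.53 CPM at P7 and P60, below its levels in microglia of the same age. Il34 was at 0 counts in whole retina at e16.5 and at 0.463 and 4.59 CPM at P7 and P60. In microglia it was too low to be tested, at 0.872 ± 0.710, 0.168 ± 0.225 and 0.0573 ± 0.0992 CPM. Csf1r itself did not pass in any comparison of ages (edgeR adjusted p = 0.991, 0.576 and 0.760 for P7 against e16.5, P60 against P7 and P60 against e16.5), with log2 fold changes of 0.20, −0.42 and −0.22 (SE 0.35 each). At each age its level was highest in replicate 1 and lowest in replicate 2, with 5807, 2730 and 4272 CPM in P7 replicates 1, 2 and 3. The fit did not pair the libraries by number, so these SE include that spread. Not passing therefore does not show an unchanged level. The growth factor gene Tgfb1 stood at 85.4 ± 21.9, 106 ± 10.1 and 137 ± 15.2 CPM in microglia and at 0.329 ± 0.121, 0.783 and 0.764 CPM in whole retina. The macrophage gene Ms4a7 stood at 2.66 ± 1.73, 4.84 ± 4.96 and 6.84 ± 5.74 CPM in microglia (SD, n = 3).

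In the authors' deposited table, 646, 2010 and 2786 genes have an adjusted p below 0.05 for P7 against e16.5, P60 against P7 and P60 against e16.5. Of the genes called here by edgeR, 31 of 32, 201 of 217 and 496 of 538 are among them, and all of those called had the same sign as in the authors' deposited table. For microglia against retina the authors' deposited table has 10129 genes at e16.5, of which 8131 are among the 10206 called here. Of these 10206 genes, 10017 have the same sign in it. The authors' deposited table has 5571 and 6896 genes at P7 and P60, where whole retina has 1 library each.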

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

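For lists, the median change over members was added as a measure only after the first measure, the median level of the members, had been seen. The results below are listed because the changes with age had opposite signs in microglia and whole retina. For single genes and median levels, every later microglia library lay beyond every earlier one, and every later retina library beyond every earlier one on the other side. The rule for median changes of lists was weaker. It asked only that the change from the mean of the earlier group had the same sign in every later library of a tissue. None of these differences was tested, since whole retina has 1 library each at P7 and P60. From P7 to P60 any retina change of the other sign therefore met the rule, however small (0.04 for Rab7b). Each value is the log2 change in microglia minus that in whole retina (CPM with 0.1 added). No group has enough libraries for a test of single libraries that stand apart.

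Between e16.5 and P7 there were 5 such results. The median level of the disease-associated list differed by 1.69 (1.56 in microglia, −0.13 in retina), taken on the log2 scale. As a median CPM the list stood in retina at 8.10, 8.07 and 7.32 at e16.5 and at 8.25 at P7, which is not lower. By the median change of its members, the retina moved the same way as microglia (0.94 against 1.62), so that the opposite direction rests on the measure. This change is taken from the mean of the log2 values at e16.5, and the list median of 0.805 reported for whole retina from the log2 of the mean CPM. The immediate early list differed by −1.51 in its median change (−0.32 in microglia, 1.19 in retina), while by median level both were higher at P7 (0.15 and 2.21), so that this too rests on the measure. Of single genes, Myo1e differed by 5.1 (3.98 in microglia), Igf1 by 4.9 (3.86) and Pmp22 by 4.28 (3.9), each lower in retina at P7.

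From P7 to P60 there were 16. The median level of the disease-associated list differed by −2.8 (−1.94 in microglia, 0.86 in retina). By the median change of its members, retina (−0.16) had the sign of microglia (−1.86). The glycolysis list differed by −2.47 in median level and by −2.26 in median change, lower at P60 in microglia (−1.92 and −1.62) and higher in retina (0.55 and 0.64). The lysosome list differed by −1.09 in median change and the apoptotic recognition list by −1.16 (retina 0.09 and 0.55). By median level the apoptotic recognition list was lower at P60 in both (−1.62 in microglia, −0.02 in retina), so that its opposite direction rests on the measure. Of glycolytic enzymes, Pgam1 differed by −3.2, Pkm by −2.97 and Pgk1 by −2.83. Spp1 differed by −9.52, with 0.854 CPM at P7 and 17.8 CPM at P60 in whole retina. Igf1 differed by −5.81, Apoe by −4.75, Ctsb by −3.92, Myo1e by −2.76 and Lipa by −2.7. Rgs7bp differed by −7.66 and Rab7b by −6.05, the latter with a retina change of 0.04.

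Between e16.5 and P60 there were 14. Of single genes lower in microglia and higher in retina, Abca1 differed by −5.5, Apoe by −4.7, Abcg1 by −3.61 and Lpl by −1.51. Ctsb differed by −2.76, the lysosome list by −0.81 in median change and Gpi1, a glycolytic enzyme, by −2.89. The endothelial and pericyte list differed by −4 (−1.3 in microglia, 2.71 in retina) and its member Pecam1 by −4.37. Rgs7bp differed by −10.75 and Cyr61 by −8.15. Higher in microglia and lower in retina were Pmp22 (5.71), Efnb1 (5.57) and Slc1a3 (2.55).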

How the results depend on the processing

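The fits with gene lengths, and DESeq2 without P7 replicate 1, were chosen only after the data had been seen. No single gene, called list or ratio recomputed under another setting was reversed. The balance of rises and falls did turn: for P7 against e16.5 from 21 up and 11 down to 159 and 169 with DESeq2 and 27 and 33 with limma-voom, and for microglia against retina from 5346 and 4860 to 4679 and 5847 on total counts and 5307 and 5964 with limma-voom. Single genes were recomputed with DESeq2, DESeq2's size factors in edgeR, a replicate block, gene lengths in edgeR and each library left out. They were not recomputed with total counts, limma-voom, other filters, fits of only 2 groups, fits of all 14 libraries or DESeq2 with gene lengths. Where recomputed, single genes stayed on their side of the threshold in 1298 cases and were no longer past it in 549. For lists, also recomputed under only part of the settings, the cases were 468 and 100. Counts of genes moved most, and the causes were not tested unless given. Counts below are in the order P7 against e16.5, P60 against P7 and P60 against e16.5, then genes highest at P7, and compare with 32, 217, 538 and 11. DESeq2 called 328, 1254, 1902 and 56 genes, which share 31, 216 and 529 with edgeR's. With gene lengths as an offset edgeR called 1, 64, 239 and 0 (141 at unadjusted p under 0.05), and DESeq2 283, 951, 1565 and 41. DESeq2 over all 14 libraries with gene lengths called 637, 1995, 2810 and 115, and its log2 fold changes correlated with those of the authors' deposited table at 0.990, 0.993 and 0.994 across genes, which are not independent. With P60 microglia in place of e16.5 as the reference group of that model the correlations were 0.967, 0.977 and 0.988 and the counts of genes 637, 1997 and 2814. Fits of only the 2 groups compared gave 143, 82 and 227, which is more than the shared fit for P7 against e16.5 and fewer for P60. Libraries agreed least at P60, with Pearson correlations of log CPM from 0.791 to 0.821. They ran from 0.855 to 0.874 at e16.5 and from 0.858 to 0.901 at P7. The shared fit takes the spread of each gene over the 3 ages together, and its part in these counts was not tested. The stricter filter gave 58 and limma-voom 60 for P7 against e16.5, and 17 and 20 genes highest at P7. Other scalings stayed within 1.5-fold. Scaling by total counts shifted the median gene by 0.22 for P60 against P7 and by 0.19 for P60 against e16.5, and gave 61 up and 99 down, and 189 up and 301 down.

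Leaving out 1 library gave 0 to 61 genes for P7 against e16.5, 41 to 217 for P60 against P7, 174 to 530 for P60 against e16.5 and 0 to 11 highest at P7. The 0 in both cases was edgeR without P7 replicate 1 (1115 and 147 at unadjusted p under 0.05, 255 and 36 with DESeq2). Other libraries that moved a count over 1.5-fold were, for P7 against e16.5, e16.5 replicates 1, 2 and 3 (6, 10 and 11), P7 replicates 2 and 3 (16 and 7) and P60 replicates 2 and 3 (50 and 61). For P60 against P7 they were e16.5 replicates 1, 2 and 3 (143, 124 and 141), P7 replicates 1, 2 and 3 (52, 110 and 41) and P60 replicates 2 and 3 (73 and 89). For P60 against e16.5 they were e16.5 replicates 2 and 3 (188 and 174), P7 replicate 1 (322) and P60 replicates 2 and 3 (341 and 340). For genes highest at P7 they were e16.5 replicates 1, 2 and 3 (1, 1 and 4) and P7 replicate 3 (1). Without 1 library, camera's adjusted p of the disease-associated list ran from 1.11e-26 to 2.86e-15, from 4.30e-16 to 2.78e-12 and, not called, from 0.109 to 0.475. For microglia against retina the count ran from 8604 to 12088.

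With a replicate block, edgeR called 367 genes for P60 against P7, and the other counts of genes and lists stayed within 1.5-fold. Of 9 pairs of libraries with the same number, 5 had deviations correlated over 0.1, so the numbers were not taken to pair the libraries, although 8 of 9 libraries correlated best with their own number, a hint from the data and not from the design. Camera with an estimated correlation sets each list's error by its own members. It gave an adjusted p of 0.191 for the disease-associated list in P60 against P7. It called 4 of the results of other lists over the 3 comparisons, against 35. These were the cell cycle and progenitor lists in P7 and P60 against e16.5. Fry, the other set test fixed beforehand, kept 20 of the 35 and no longer called 15. For the disease-associated list fry gave adjusted p of 0.00205 for P7 against e16.5, 0.00182 for P60 against P7 and 0.276 for P60 against e16.5. The median log2 ratio of rod genes between microglia and whole retina at P7, as a mean over 3 libraries, went from −4.67 to −5.00 on total counts. In counts simulated at the depth and spread of these libraries, 51.5% of 8-fold changes and 0% of 2-fold changes were recovered for P7 against e16.5, and the parts of depth and spread in this were not separated.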

Other observations

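Whole retina alone differed in its cell type genes between e16.5 (SD, n = 3), P7 and P60 (1 library each, no test). The e16.5 libraries were made from central retina, per the labels, so the retinal region may differ together with age. The photoreceptor gene Pdc, which encodes phosducin, stood at 25.2 ± 2.15, 961 and 1315 CPM. Genes of dividing progenitors were lower at each later age, with Mki67 at 649 ± 71.1, 99.8 and 0.297 CPM and Ccnd1 at 4213 ± 280.4, 454 and 26.5 CPM. The neurogenic transcription factor gene Atoh7 went from 571 ± 91.5 to 1.46 and 0.425 CPM. The Mueller glia gene Rlbp1 stood at 12.9 ± 3.38, 289.7 and 380.0 CPM, and the glutamine synthetase gene Glul at 697 ± 37.3, 275 and 2569 CPM.

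By list, cell cycle genes stood lower in whole retina by a median log2 ratio of −3.385 at P7 against e16.5 and −2.959 at P60 against P7, and progenitor genes by −1.711 and −1.445, all at percentile 0 of 10000 matched random lists. Immediate early genes stood higher by 1.181 (percentile 99.09) and 0.41 (percentile 99.6). Glycolysis genes stood at −0.685 (percentile 7.22) and 0.637 (percentile 98.76). Cholesterol and lipid genes stood at −1.697 (percentile 0) and 0.127 (percentile 89.64). The gene Ccnb1ip1 was at 6713 ± 442 CPM in whole retina at e16.5 and at 0.321 ± 0.328 CPM in microglia (SD, n = 3).

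The tests below of other macrophages and of transcript lengths, and of carryover as the whole cause of the cell cycle fall, were chosen only after the result was seen. The disease-associated list stood highest at P7, with a median log2 fold change of 1.52 from e16.5 and of −1.86 to P60. Carryover of RNA from the surrounding retina is argued against, since 6.70% of the whole retina level came to 0.187% of the microglia level at P7 for the median member and to 11.4% for the highest. Transcript lengths that differ between libraries are argued against for the list, whose medians with lengths as an offset were 1.54 and −1.75, at least 0.94 of those without. For the 11 genes highest at P7 the calls ended with that offset because the errors grew, with median log2 fold changes of 2.23 (SE 0.311) before and 2.10 (SE 0.443) after from e16.5 and of −3.50 (SE 0.335) and −3.42 (SE 0.476) to P60, and edgeR adjusted p of 0.0739 to 0.435 and 0.00244 to 0.104. Border-associated macrophages or monocytes may have entered the sort at P7 although it removed CCR2-positive cells: the median change of their 15 markers was 0.839 with an interquartile range of 2.16 and a span from 4.78 (Ace) to −7.66 (Lyve1), among them Fn1 (2.25, 176 ± 27.3 CPM at P7), Maf (−0.18, 495 ± 6.11 CPM) and Mrc1 (−0.66, 21.6 ± 3.32 CPM), so that they and a change of the microglia with age, which was not tested, cannot be told apart. That median is above the bound of 0.759, which is 0.5 of the list's median, but not by its spread. That it must pass by its spread was required only after the value had been seen, and without this the explanation would have passed.

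Between e16.5 and P7, the medians of 6 of the 7 retinal cell lists in the sorted microglia had the sign of whole retina, and the median marker stood at 8.02%, 6.70% and 3.30% of the retina level at e16.5, P7 and P60. Carryover of retinal RNA could account for this if rod genes and the other retinal lists stood at a common ratio to whole retina. A range for this was set at P60 only. At P7 the median log2 ratio was −4.67 for rod genes and −3.60 for the other retinal lists, as means over 3 libraries. At P60 the median log2 ratio of rod genes less that of the other lists was −0.145 as a mean over 3 libraries. It was −1.03, 0.65 and −0.05 in P60 replicates 1, 2 and 3. Since 1 library lies outside the range set for a common ratio, carryover and other sources of these transcripts cannot be told apart, and no change of the microglia with age was tested.

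The cell cycle list fell from e16.5 to P7 by a median log2 fold change of −2.08 in microglia (SD 0.77 over members) and stood lower in whole retina too. Carryover from dividing retinal progenitors may contribute, since 8.02% of the whole retina level at e16.5 came to 19.5% of the microglia level for the median member and to 113% for the highest. As the whole cause it is argued against, since losing all of it would lower the median member by a log2 fold change of −0.314. A change of microglial division with age stays open as a hypothesis and was not tested.

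Other splits of the libraries were tested with edgeR. The 6 libraries of each comparison of 2 groups make 10 splits into 3 and 3, too few for a share under 0.05. In each of the 4 comparisons 1 of the 10 splits, the real one, reached the real count, which was 32, 217, 538 and 10206 genes, and the highest of the others was 0. For the genes highest at P7, 1 of 60 assignments of the 9 libraries to 3 groups, the real one with 11, gave as many. The highest of the others was 1. This share is under 0.05, but it concerns only the division of the libraries by age as a whole. Mixed assignments put the differences between ages into the spread, so this does not test the 11 genes apart from those differences or from the shared P7 libraries, and edgeR called 0 without P7 replicate 1 (147 at unadjusted p under 0.05 at both steps, 36 with DESeq2).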
